A study of Mus musculus with 2 samples.

How the data were processed

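Long-read RNA sequencing was done on adrenal gland tissue of female B6CASTF1/J mice at 36 days of age. The 2 libraries form 1 group, taken from the tissue, sex, strain and age in the labels, and carry the labels' own numbers as biological replicates 1 and 2. Replicate 1 started from 1 µg of RNA per the labels, and the labels used here give no quantity for replicate 2. Spike-in RNAs were added to both, per the labels an Ambion mix and a Lexogen set. The Lexogen species were not analysed here. A label field gives the same animal number for both libraries, and another gives different numbers, so p-values and spread refer to these libraries.

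Each library came with a table of transcript models and an annotation of their exons. Per the labels' protocols, the reads went through the ENCODE long-read RNA-seq pipeline for mouse. The values used are counts of whole reads per transcript model as the authors deposited them, with no normalization, and only models with at least 1 read are listed. Per the file headers and accompanying notes, reads were aligned to mm10 and models were compared with GENCODE release M21, and each library was processed on its own. The annotation files name TALON as the source of the models and of their classes. The aligner, the versions of the tools and any filter on models are not given in the sources used here. Numbers of exons and lengths in bp were taken from the deposited tables per the file headers. Reads that align equally well to near-identical genes were assigned upstream, and how is not given in the sources used here. Gene levels of such copies are therefore uncertain.

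Gene counts were sums over the models of a gene. The unit used for levels is CPM, reads per 1000000 reads of annotated genes, leaving out spike-ins and loci outside the annotation. Spike-ins were 2.12% and 3.65% of all reads in replicates 1 and 2, antisense loci 3.61% and 3.98%, and intergenic loci 0.743% and 1.00%. Models of the classes Known, NIC and NNC were called full-length. Ratios of replicate 2 to replicate 1 used CPM scaled by TMM factors of 1.03 and 0.976 with a pseudocount of 1. Total reads were 1223776 and 453761, and 3 reads, the floor for a count of 0, equal 2.62 and 7.24 CPM. A fold against 0 reads was computed against that floor per library.

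Agreement was measured over genes with at least 10 reads in total, as Pearson's r and Spearman's rho of log2(CPM + 1) and as the common dispersion of an intercept-only edgeR fit. Reads of each gene were compared between the libraries with a two-sided exact binomial test against the share expected from the scaled library sizes. P-values were adjusted by Benjamini-Hochberg over 9885 genes, with a threshold of 0.05, and again over each gene list alone. A count model with replicates cannot be fitted between single libraries. The test sets reads against counting error and says nothing of mice in general. For 29 gene lists fixed before the data were examined, the median log2 ratio of members with a mean CPM of at least 1 was ranked among 10000 random lists of the same size, matched on mean level in 10 bins. Lists needed at least 3 such members. One list member, Ahsp, was not matched to the annotation by its symbol. Isoform shares were compared in genes with at least 20 full-length reads in each library, using a two-sided Fisher's exact test of the leading isoform against all others. Intervals of shares are 95% Wilson intervals. Unannotated spliced models with at least 2 reads in a library were looked up in the other, where 1 read was enough, by identical intron chains, since their identifiers are numbered per library and 0 of 35575 and 14930 were shared. Loci outside the annotation were matched by overlap on the same strand. Length classes used the most read annotated transcript of each gene, with limits at 1, 2 and 3 kb, and 1000 bootstrap draws gave the interval of each median. The tests of reads and of isoforms, the intervals of shares and the floors cover counting error only. Bootstrap intervals of medians cover spread across genes. Permutation p-values and the interval of the slope for spike-ins cover spread across spike-ins.

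Genes named in the text followed a rule fixed before the data were examined. It took the 20 genes with the highest mean CPM, the 4 highest members of each list, members of the steroidogenesis, zona glomerulosa, X-zone and medulla lists at a mean of at least 10 CPM, and absent members of the sex-linked and the ovary and testis lists. It added the 6 largest and 6 smallest ratios among genes with at least 50 reads, an adjusted p under 0.05 and an absolute log2 ratio of at least 1. Isoforms were named for list genes with at least 50 full-length reads in each library and for the 6 genes with the widest difference of leading share. The 8 most read unannotated models and the 4 most read loci found in both libraries completed it. Malat1 was chosen after its values were seen. Values of some genes that the rule takes are not reported here.

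The tests were checked on simulated data. With 200 genes changed, 21.5% of those changed by 2-fold (n = 93) and 70.5% of those changed by 4-fold (n = 95) were called, and 3.33% of 90 calls were false. With no change and the spread estimated here, 1687 of 9786 genes were called. The isoform test recovered 63.5% of 200 simulated shifts from 80 to 50 percent, with 4.51% of 133 calls false. Unchanged genes had a leading share of 80% there, and reads were drawn with counting error alone. The rate of false calls therefore leaves out spread between libraries, and no isoform simulation with such spread was run. Of 100 random lists without a shift, 6 fell outside the central 95%, and of 100 lists shifted by 1 on the log2 scale, 97 lay above it. A simulated coefficient of variation of 30.7% was estimated as 29.9%.

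Alternatives comprised DESeq2 size factors or total reads for scaling, other read minimums, full-length reads alone, leaving out the Genomic class, and thinning the deeper library to equal depth. Other pseudocounts, list summaries, isoform thresholds and tests, and each library alone were also tried. Read classes in models of more than 1 exon alone were planned too. The same restriction for gene tests and the cortex to medulla ratio, a count of genes with any 2 isoforms at the minimum share, and values without Cyp11a1 were added after the data were seen. Computations used R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.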

Results

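RNA of the mouse adrenal gland was sequenced as long reads, in which 1 read can span a transcript from end to end. The tissue came from female B6CASTF1/J mice, the first-generation hybrids of C57BL/6J and CAST/EiJ, at 36 days of age. The labels place both libraries in 1 group and number them as biological replicates 1 and 2, so that the design holds no comparison between conditions. The question it can answer is which transcripts the gland holds and how closely both libraries repeat one another. One label field names the same animal for both libraries while another names different animals, so the spread and the p-values given here measure these 2 libraries and may be technical.

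Replicate 1 held 1223776 reads and replicate 2 held 453761. Of these, 1144572 and 414588 reads fell on genes of the reference annotation, a 2.76-fold difference in depth. A count of 0 allowed a level of up to 2.62 reads per 1000000 reads of annotated genes (CPM) in replicate 1 and 7.24 CPM in replicate 2, taken as 3 reads. At least 1 read was found for 16027 and 13678 annotated genes, with 12760 genes in both libraries, or 7960 at a minimum of 5 reads in each. Intervals of shares and floors cover counting error only, and the reads carry no stated molecular identifiers. Unless another measure is named, levels are mean CPM ± SD over both libraries (n = 2), and coordinates refer to the mouse genome build mm10 (GRCm38).

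Known transcripts made up most reads. Models whose splice junctions match an annotated transcript held 70.1% ± 3.77 of the reads, 72.7% in replicate 1 (95% Wilson interval 72.7% to 72.8%) and 67.4% in replicate 2 (67.3% to 67.6%). The class of incomplete splice matches (ISM), named for models that hold a consecutive part of an annotated junction chain, held 11.1% and 14.9%. Models of 1 exon, which have no junction, made up 20.6% and 40.6% of the reads in this class. Unannotated models built from known splice sites (class NIC) held 3.24% and 2.92%, and those with at least 1 splice site outside the annotation (class NNC) held 2.78% and 2.51%. Reads overlapping introns without a matching splice pattern, the Genomic class, held 6.02% and 7.42%. Models with 1 exon took 18.8% of the reads in replicate 1 and 25.9% in replicate 2, and the spike-in RNAs of the Ambion mix took 2.12% and 3.65%. Without the reads of Cyp11a1, a setting chosen after the data were seen, ISM reads were 11.2% and 12.2%, a narrower gap, and Genomic reads were 5.17% and 7.71%, a wider one.

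**Figure D1:**
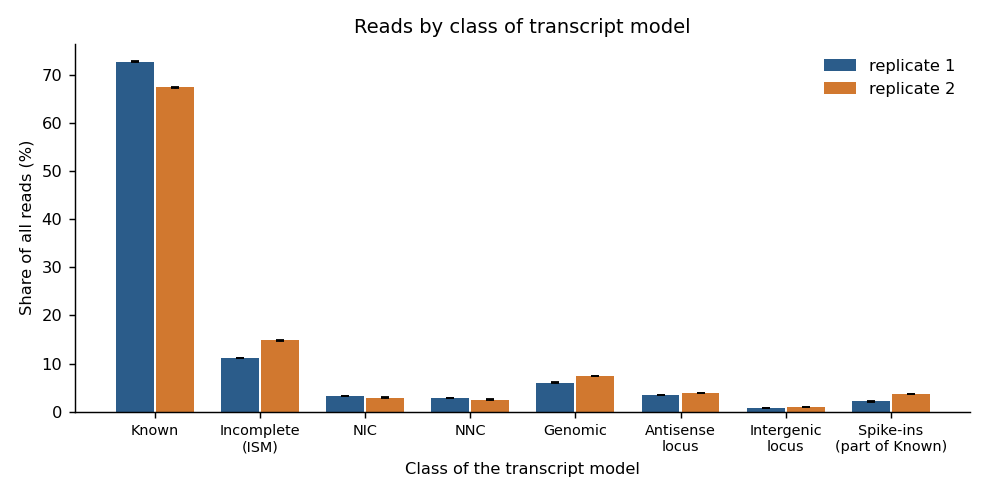
Share of all reads (%, vertical axis) in each class of transcript model (horizontal axis) for replicate 1 (blue) and replicate 2 (orange), with 95% Wilson intervals as error bars. Known models hold 72.7% and 67.4% of the reads and incomplete models 11.1% and 14.9%.

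Genes of adrenal steroid synthesis were the most abundant functional list. Cyp11a1, which cleaves the cholesterol side chain in the first step of steroid synthesis, was the most abundant gene at 31089 ± 14535 CPM. It was followed by Cyp21a1, the steroid 21-hydroxylase, at 13209 ± 802 CPM, by Hsd3b1, a 3-beta-hydroxysteroid dehydrogenase, at 10129.9 ± 775 CPM, and by Star, which carries cholesterol into mitochondria, at 9741 ± 1332 CPM. Cyp11b1, which makes corticosterone, reached 8209 ± 114 CPM. Counted per 1000000 full-length reads, that is reads of Known, NIC and NNC models, the order differed, with Cyp21a1 at 13964 ± 620, Cyp11a1 at 10612 ± 804, Star at 9321 ± 1509.9, Cyp11b1 at 8727 ± 70.9 and Hsd3b1 at 457 ± 263. The electron carriers of the mitochondrial steroid enzymes were Fdx1 at 1781 ± 401 CPM and Fdxr at 1271 ± 436 CPM. The transcription factor Nr5a1 was at 699 ± 112 CPM and the corticotropin receptor Mc2r at 91.3 ± 43.9 CPM. Together the 13 genes of the steroidogenesis list held 77814 ± 12288 CPM, or 7.78% ± 1.23 of the reads of annotated genes.

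The gene Cyp11a1 has the identifier ENSMUSG00000032323.13 and lies on chromosome 9 from 58006411 to 58027023. Cyp21a1 lies on chromosome 17 from 34801348 to 34804561, Hsd3b1 on chromosome 3 from 98852194 to 98859794, Star on chromosome 8 from 25806555 to 25815982 and Cyp11b1 on chromosome 15 from 74834125 to 74841643. Reads of Cyp11b1 and Cyp11b2, of Hsd3b1 and Hsd3b6, and of the Akr1c family come from near-identical copies, and their split between copies is uncertain.

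Markers of all cortical zones were read. Among the zona fasciculata genes, 8 of 9 had a read and summed to 32672 ± 1513 CPM, led after Hsd3b1, Star and Cyp11b1 by the efflux pump Abcb1b at 2255 ± 437 CPM. Hsd3b1, Star, Cyp11b1 and Mc2r are also members of the steroidogenesis list, so these sums overlap and do not measure the size of zones. Of the zona glomerulosa list, all 12 members were read and summed to 3477 ± 981 CPM. The potassium channel Kcnk3 made up most of it at 2504 ± 941 CPM, and Wnt4 and Cyp11b2, the aldosterone synthase, stood at 333 ± 47.4 and 297 ± 16.9 CPM. Cyp11b1 exceeded Cyp11b2 by 27.7-fold ± 1.97 (29.1 and 26.3 in the libraries). The 6 genes listed for the X-zone, the transient inner zone of the mouse cortex that persists in young females, summed to 12171 ± 1955 CPM. Akr1c18, which inactivates progesterone, reached 7916 ± 1014 CPM and Akr1cl 3570.4 ± 951 CPM, while Cyp2f2 and Pik3c2g were at 456 ± 20.9 and 208 ± 4.53 CPM. The 13 capsule and stroma genes summed to 598 ± 187 CPM, with the collagen Col3a1 at 225 ± 75.4 CPM and the proteoglycan Dcn at 119 ± 42.5 CPM.

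The catecholamine-producing medulla was read in both libraries. All 24 medulla genes had a read, and they summed to 10546 ± 2173 CPM. The granins Chga, at 3225 ± 1030.2 CPM, and Chgb, at 3101 ± 784 CPM, led the list. Th, the rate-limiting enzyme of catecholamine synthesis, was at 1417 ± 370 CPM, Scg2 at 849 ± 154 CPM, Npy at 651 ± 6.87 CPM and Pnmt, which turns noradrenaline into adrenaline, at 442 ± 62.7 CPM. Th exceeded Pnmt by 3.18-fold ± 0.386. Summed steroidogenesis genes exceeded summed medulla genes by 7.66-fold ± 2.74 (5.72-fold in replicate 1 and 9.60-fold in replicate 2). Counting full-length reads alone gave 4.49-fold. The ratio of median levels of the members was 45.0-fold ± 26.0, with the libraries in the opposite order (63.4-fold in replicate 1 and 26.6-fold in replicate 2).

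Of the lists for cell types outside the cortex and medulla, adipocyte genes had the highest sum. They held 10358 ± 2263 CPM over 12 genes, below the medulla list in replicate 1 (8758 against 12082 CPM) and above it in replicate 2 (11959 against 9009 CPM). The list was led by the carbonic anhydrase Car3 at 2633 ± 106 CPM, the adipsin gene Cfd at 1877 ± 163 CPM, the fatty acid binding protein Fabp4 at 1843 ± 1515 CPM (709 ± 110 per 1000000 full-length reads) and Cidea at 1199.9 ± 575 CPM. Of 8 erythroid genes, 5 had a read and summed to 3939 ± 134 CPM. The globin Hba-a1 led at 2057 ± 10.6 CPM, and reads of the near-identical globin copies are not separable with certainty. Endothelial genes summed to 771 ± 29.3 CPM, with Plvap at 270.1 ± 27.4 CPM, and macrophage genes to 504 ± 47.4 CPM, with Cd74 at 177 ± 15.1 CPM and Lyz2 at 104 ± 27.4 CPM. Schwann and glial genes summed to 31.3 ± 3.49 CPM and lymphocyte genes to 22.4 ± 5.79 CPM. The liver and pancreas list reached 83.5 ± 5.50 CPM, of which the elastase Cela1 alone held 70.9 ± 8.86 CPM. Of the 10 kidney genes, 2 had a read, summing to 2.52 ± 0.148 CPM.

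Genes of sex steroid cells were near or under the floor. Of the 8 genes listed for ovary and testis steroid cells, 3 had a read, and the list summed to 3.29 ± 2.18 CPM. Cyp17a1, the 17-alpha-hydroxylase that the adult mouse adrenal lacks, had 0 reads in replicate 1 and 2 reads in replicate 2. The aromatase Cyp19a1, the gonadotropin receptors Lhcgr and Fshr, and Amh and Zp3 had 0 reads in both libraries, which allows up to 2.62 and 7.24 CPM. Among sex-linked genes, Xist, the RNA of the inactive X chromosome, had 31 and 21 reads, none in full-length models, and the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had 0 reads in both.

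Metabolic and regulatory lists were read as follows. Nuclear genes of mitochondrial oxidative phosphorylation summed to 22783 ± 2239 CPM, led by the ATP synthase subunit Atp5b at 3664 ± 147 CPM and Cox4i1 at 3181 ± 918 CPM, and the 25 cytosolic ribosome genes to 14937 ± 564 CPM. Antioxidant genes reached 8439 ± 479 CPM, with the peroxiredoxins Prdx1 at 1709.7 ± 65.4 CPM and Prdx2 at 1257 ± 328 CPM. Genes of cholesterol uptake, storage and release summed to 6226 ± 627 CPM, of which Apoe held 3171 ± 1114 CPM and the lipoprotein receptor Scarb1 1053 ± 381 CPM. Cholesterol synthesis genes summed to 3463 ± 923 CPM, led by Fdps at 556 ± 281 CPM. Heat shock and unfolded protein genes summed to 4097 ± 1073 CPM, led by the chaperone Hspa8 at 1674 ± 608 CPM, and immediate early genes to 1934 ± 106 CPM, led by Jund at 708 ± 118 CPM. Imprinted and developmental genes held 2022 ± 578 CPM, of which the cell cycle inhibitor Cdkn1c held 1423 ± 454 CPM and Dlk1 366 ± 16.8 CPM. Circadian genes summed to 699 ± 37.7 CPM, with Dbp at 358 ± 19.2 CPM, cell cycle genes to 401 ± 28.3 CPM, with Tubb5 at 186 ± 18.1 CPM, and interferon genes to 343 ± 23.7 CPM, with Ifitm3 at 117 ± 25.1 CPM. Outside the lists, the alcohol dehydrogenase Adh1 at 4765 ± 237 CPM, the ubiquitin gene Ubb at 3850.4 ± 216 CPM, the transcription factor Cebpb at 3516 ± 896 CPM and the ferritin Fth1 at 3489 ± 490 CPM were among the 20 most abundant genes.

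**Figure D2:**
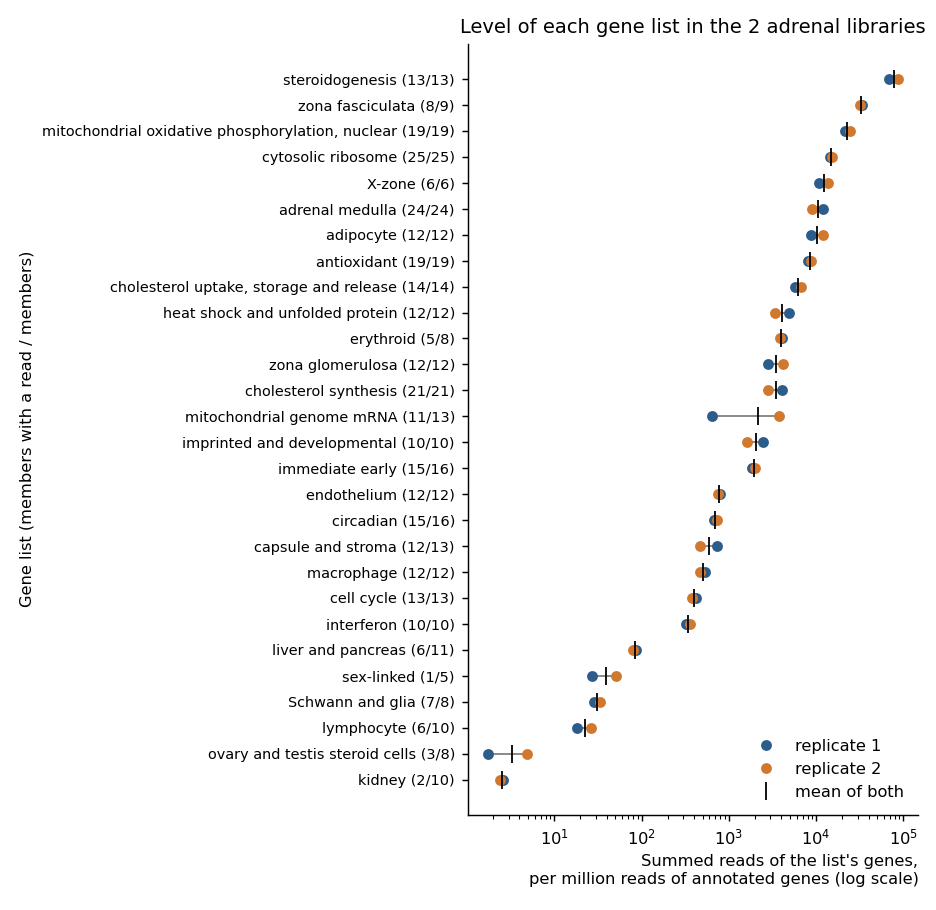
Summed level of each gene list apart from the isoform panel (horizontal axis, log scale, reads per 1000000 reads of annotated genes) in replicate 1 (blue) and replicate 2 (orange), with the mean as a black bar. Each list name gives the number of members with a read and the number of members. Of the lists drawn, steroidogenesis genes lead at 77814 CPM, and the mitochondrial genome list shows the widest gap on this scale, 633 against 3727 CPM.

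Gene levels repeated between the libraries with a spread beyond counting error. Across 9885 genes with at least 10 reads in total, Pearson's r of log2(CPM + 1) was 0.868 and Spearman's rho was 0.867. These are correlations across genes, which are not independent replicates. The chi-square of the counts was 6.67 per degree of freedom, so the libraries differed by more than sampling noise, and edgeR put the coefficient of variation between them at 30.7%. An exact binomial test of the reads of each gene, which compares these libraries and no conditions, called 1383 of the 9885 genes (14.0%) at an adjusted p under 0.05. Of these, 777 were higher and 606 lower in replicate 2, and 750 of them differed by at least 1 on the log2 scale. The balance turned with total reads as scaling (650 higher and 728 lower), with reads thinned to equal depth (492 and 516) and in models of more than 1 exon (604 and 616), a setting chosen after the data were seen. When libraries with no difference beyond a coefficient of variation of 30.7% were simulated, the same test called 1687 of 9786 genes. Spread of that size alone can thus give such a count. The simulation is no separate evidence, since its spread was estimated from these same libraries.

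The genes furthest apart included a set known from skeletal muscle and a set of mitochondrial and pseudogene transcripts. Atp2a1, the calcium pump of fast muscle fibres, had 179 reads in replicate 1 and 0 in replicate 2, at least 21.6-fold lower against a floor of 3 reads. Troponin C2 (Tnnc2), with 119 and 0 reads, was at least 14.4-fold lower, and titin-cap (Tcap), with 61 and 0 reads, at least 7.37-fold lower. Skeletal alpha-actin (Acta1) had 365 reads against 1 and the muscle creatine kinase Ckm 278 against 1. Mir1906-1, annotated as a miRNA gene on chromosome 12 from 109544541 to 109544620, had 71 and 0 reads and was at least 8.57-fold lower. Which transcript the reads counted for Mir1906-1 come from was not tested. In the other direction, Nr4a1, an immediate early nuclear receptor, had 62 reads in replicate 1 and 178 in replicate 2, 8.19-fold higher in the latter (log2 ratio 3.03, adjusted p of the exact binomial test 7.0e-53). The cytochrome b gene of the mitochondrial genome, mt-Cytb, was 10.7-fold higher (113 and 419 reads). The pseudogenes Gm14539 (25 and 176 reads) and Gm10231 (19 and 110 reads) were 19.6-fold and 15.9-fold higher, and the pseudogene Gm10774 had 1 and 115 reads. Gm7247, annotated as protein-coding (7 and 64 reads), was 22.9-fold higher, with 0 of these reads in full-length models. Reads of pseudogenes and of their parent genes are hard to separate. Malat1, a nuclear RNA of 1 exon chosen after its values were seen, had 4333 reads in replicate 1 and 34 in replicate 2.

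**Figure D3:**
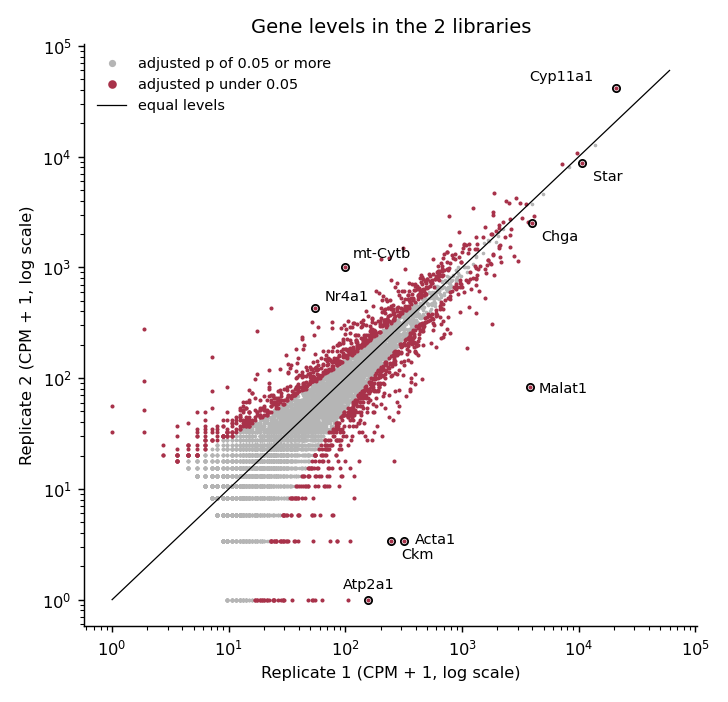
Level of each gene tested in replicate 1 (horizontal axis) and replicate 2 (vertical axis), as CPM + 1 on log scales, with genes at an adjusted p under 0.05 in the exact binomial test in red. The line marks equal levels; Acta1, Ckm and Atp2a1, with 1, 1 and 0 reads in replicate 2, lie near the lower edge, and Nr4a1 and mt-Cytb lie above the line.

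Steroidogenesis genes moved in both directions between the libraries. Of the 13 members, 3 were higher in replicate 2 (Cyp11a1 by 2.09-fold, Hsd3b1 by 1.17-fold and Mrap, a partner of the corticotropin receptor, by 0.74 on the log2 scale), 4 were lower (Star, Fdx1, Fdxr and Mc2r, at log2 ratios of -0.21, -0.39, -0.64 and -0.94) and 6 did not pass the test. Adjusted over the list alone, 4 were higher and 7 lower. The median log2 ratio of the members was -0.053, while the log2 ratio of their summed CPM was 0.39, with Cyp11a1 the largest part of the sum. In full-length reads the median was -0.31 (percentile 3.15 of matched random lists, against 30.5 over all reads). There, Cyp11a1 and Hsd3b1 were lower in replicate 2 instead, at -0.14 and -1.23, and without the Genomic class Star was at -0.053 and did not pass. In the zona fasciculata list, 2 of 8 tested members were higher and 5 lower, both over all genes and adjusted over the list alone. In the zona glomerulosa list, 3 of 10 were higher and 0 lower by either adjustment, with Kcnk3 at a log2 ratio of 0.86 and the endocytic adaptor Dab2 at 1.12. With reads thinned to equal depth Dab2 was at 0.75 and did not pass, and in full-length reads it was at 2.41. In the X-zone list, 3 of 6 were higher and 0 lower by either adjustment. Among these, Akr1c18 (0.33) and Akr1cl (0.62) turned to -0.12 and -0.015 in full-length reads.

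Of 21 medulla genes tested, 3 were higher in replicate 2, 4 lower and 14 not past the threshold, with the same counts adjusted over the list alone. Those lower were Th, Chga, Chgb and Cyb561 (log2 ratios -0.47, -0.59, -0.45 and -0.80), and those higher included Scg2 (0.44). Of 12 adipocyte genes, 4 were higher and 0 lower, and 5 were higher adjusted over the list alone. Of those that passed over all genes, Fabp4 (log2 ratio 1.99) and Cidea (1.09) moved most, and in full-length reads their ratios were 0.33 and 0.63. The other 2, Car3 (0.15) and Cfd (0.25), did not pass with reads thinned to equal depth. Endothelial genes gave 0 higher and 2 lower of 11, or 1 and 2 adjusted over the list alone, and Emcn (-0.92) was no longer past the threshold in full-length reads, without the Genomic class or at equal depth. Capsule and stroma genes gave 0 higher and 1 lower of 10, or 0 and 4 adjusted over the list alone, and macrophage genes 1 higher and 0 lower of 9 by either adjustment. None of the 5 erythroid genes, 9 cell cycle genes or 8 interferon genes passed, over all genes or adjusted over the list alone, although Hba-a1 passed without the Genomic class (0.19) and the interferon gene Bst2 in full-length reads (-1.05). No call over all genes or over the list alone was made for the single genes tested in the Schwann and glia, lymphocyte, and liver and pancreas lists. The kidney list and the ovary and testis list held no gene with enough reads. Xist was not past the threshold over all genes (log2 ratio 0.95, exact binomial test, adjusted p 0.123) and passed adjusted over the list alone, where it was the single gene tested.

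Mitochondrial genome transcripts stood highest of the lists in replicate 2. All 9 tested were higher, by either adjustment, with a median log2 ratio of 2.45 over 11 members (percentile 100 of 10000 random lists matched on level), and their sum was 633 CPM in replicate 1 and 3727 CPM in replicate 2. Besides mt-Cytb, mt-Co1 was at a log2 ratio of 2.45, mt-Nd2 at 2.14 and mt-Nd1 at 2.71. Nuclear copies of mitochondrial sequence can share these reads. Cholesterol synthesis was the 1 list below the central range, with a median of -0.304 over 21 members (percentile 2.44, against a limit of 2.5). Lists just inside the limit had lower medians. These were heat shock and unfolded protein (-0.325, percentile 3.65) and liver and pancreas (-2.14 over 5 members, percentile 2.73). Of the 21 cholesterol synthesis genes, 2 were higher and 6 lower, or 2 and 7 adjusted over the list alone. The lower genes included Hmgcs1 (-1.33), which makes the precursor of mevalonate, Fdps (-1.01) and Msmo1 (-0.41), while Dhcr7, the last enzyme of the pathway, was higher (0.44). In full-length reads Msmo1 (-0.36) and Dhcr7 (1.05) did not pass, and Msmo1 did not pass without the Genomic class (-0.34) or at equal depth (-0.45) either. Of 26 lists with a percentile, the mitochondrial genome and cholesterol synthesis lists, 2 in all, lay outside the central 95% of random lists, where chance gives 1.3. With members at a mean of at least 10 CPM, 5 of 23 lists did.

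Over all genes, the oxidative phosphorylation, immediate early, cholesterol uptake, antioxidant, ribosomal and isoform panel lists held members higher and members lower in replicate 2, while the heat shock, circadian and imprinted lists had calls in 1 direction. Nuclear oxidative phosphorylation genes gave 9 higher, 4 lower and 6 not past, or 10 and 5 adjusted over the list alone. Ndufa4, at a log2 ratio of 1.55 (0.73 in full-length reads), and Cox4i1, at 0.67, were among those higher, and Atp5a1, at -0.66, among those lower. Heat shock and unfolded protein genes gave 0 higher and 5 lower of 12, or 0 and 6 adjusted over the list alone, with Hspa8 at -0.69. Immediate early genes gave 4 higher and 2 lower of 12, or 4 and 3 adjusted over the list alone, and Nr4a1 and Jund (0.41) were higher while Jun (-1.92) was lower. Cholesterol uptake, storage and release genes gave 3 higher and 2 lower of 13 by either adjustment, with Apoe higher (0.80) and Scarb1 lower (-0.68). The Apoe ratio was -0.11 in full-length reads. Antioxidant genes gave 3 higher and 1 lower of 19, or 4 and 1 adjusted over the list alone, and Prdx2 (0.61) did not pass in full-length reads (0.23). Ribosomal genes gave 4 higher and 4 lower of 25 by either adjustment, with Rpl5 at 2.35. Circadian genes gave 2 higher and 0 lower of 11, or 2 and 1 adjusted over the list alone. Imprinted genes gave 0 higher and 2 lower of 5 by either adjustment, Cdkn1c (-0.59) and the noncoding RNA Meg3 (-1.16, or -2.79 in full-length reads). The 34 genes chosen for isoforms gave 6 higher and 13 lower of 31, or 6 and 16 adjusted over the list alone.

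The most read model of Cyp11a1 was not its full-length transcript. Cyp11a1-201, with 9 exons and 2120 nt, spans 58014671 to 58027023 on the plus strand of chromosome 9. In replicate 1, 11553 of 23820 reads (48.5%) lay in a model of 1 exon at 58025096 to 58027023, classed as Genomic. In replicate 2, 13213 of 17150 reads (77.0%) lay in a model of 1 exon at 58025078 to 58027023, classed as ISM. The model of replicate 2 covers the last 4 exons of Cyp11a1-201 and the introns between them. That of replicate 1 covers the same stretch apart from the first bases of the first of these exons. Full-length reads of Cyp11a1 made up 44.0% (95% Wilson interval 43.4% to 44.6%) and 18.4% (17.8% to 18.97%). Expressed per 1000000 full-length reads, its level was 11180.0 in replicate 1 and 10044 in replicate 2.

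**Figure D4:**
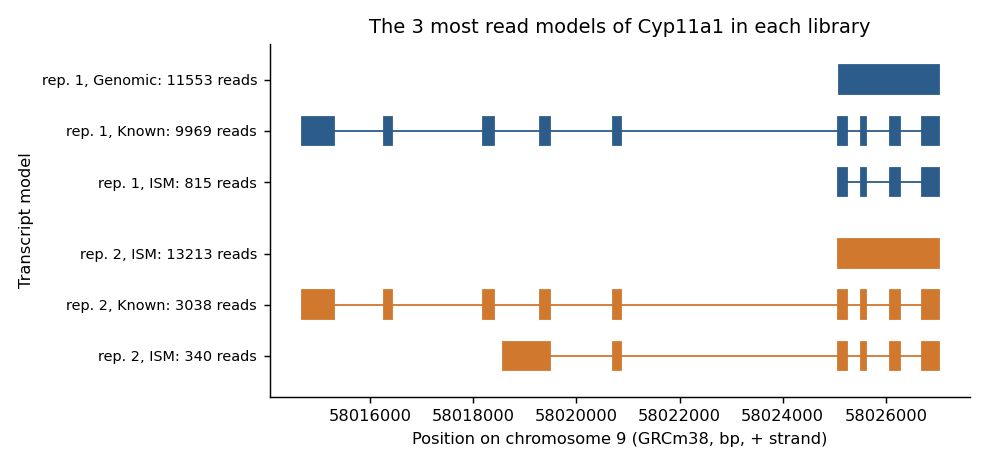
Position on chromosome 9 (horizontal axis, bp, GRCm38) of the 3 most read models of Cyp11a1 in replicate 1 (blue) and replicate 2 (orange), with boxes as exons and lines as introns. A model of 1 exon over the last 4 exons holds 11553 and 13213 reads, and the full-length model of 9 exons holds 9969 and 3038.

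Hsd3b1 was read mostly in models classed as incomplete. Full-length models held 5.50% of its reads in replicate 1 (603 of 10967) and 1.92% in replicate 2 (85 of 4427). Models lacking the 5' part of the annotated junction chain, ISM suffix models, held 85.3% and 70.3%. The leading one had 4 exons on the minus strand of chromosome 3, from 98851594 to 98858341 in replicate 1 (8331 reads) and from 98852194 to 98858341 in replicate 2 (2677 reads). Suffix models held more of the reads in replicate 2 for several other genes. Their share was 15.1% and 52.0% for Atp5b, 20.7% and 52.0% for Akr1cl, 16.1% and 40.8% for Akr1c18, 32.7% and 79.6% for Fabp4, and 24.3% and 58.6% for Ndufa4. For Aldoa, the aldolase, it was lower in replicate 2, at 20.2% and 10.2%, and for Car3 it was 3.62% and 2.49%. For Apoe, models of 1 exon held 18.2% and 58.0% of reads.

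Most genes used 1 leading isoform. Among 3015 genes with at least 20 full-length reads in each library, the leading isoform held a median of 92.7% of full-length reads in replicate 1 and 92.3% in replicate 2, and it was the same isoform in both libraries for 2927 genes (97.1%). It was an annotated transcript in 2946 genes and an unannotated model in 69. The isoform ranked second by mean share reached 10% of the full-length reads in both libraries in 593 genes (19.7%), and in 83 genes at least 3 isoforms did. With each library taken alone, 1742 of 5740 genes with enough reads met this share in replicate 1 (30.3%) and 779 of 3029 in replicate 2 (25.7%), and 81 of 615 genes (13.2%) did in both at a minimum of 100 full-length reads. The second isoform was an unannotated model in 105 of the 593.

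Several genes of steroid and catecholamine synthesis were read mostly as 1 isoform. Cyp11a1-201 held 95.2% and 96.4% of the full-length reads of its gene in replicates 1 and 2, Cyp21a1-201 94.7% and 95.2%, Star-201 98.6% and 98.3%, Cyp11b1-201 96.1% and 96.5%, Th-201 94.8% and 95.6%, Pnmt-201 98.6% and 98.5%, and Chga-201 95.8% and 96.3%. Fdxr-201 held less, at 86.3% and 88.5%, and Nr5a1-201 held 70.0% and 71.4%. The steroid enzyme Hsd3b1 divided its full-length reads between Hsd3b1-201 (59.9% and 35.3%) and other models, of which an unannotated NNC model of 4 exons held 8.29% and 34.1%. Full-length reads were only 5.50% and 1.92% of the reads of Hsd3b1. Its ISM suffix models, with 85.3% and 70.3% of the reads, are outside these shares, so the main isoform of the gene stays open. Other genes divided their reads too. Gnas, encoding the stimulatory G protein subunit, was read as Gnas-208 (54.4% and 58.2%) and Gnas-207 (26.8% and 21.4%). Scg2 was read as Scg2-202 (48.7% and 56.6%) and Scg2-201 (49.6% and 42.8%), which have 3 and 2 exons. Pkm, the pyruvate kinase, used Pkm-201 (74.8% and 67.6%) and Pkm-202 (20.1% and 25.3%). Cyb561, a cytochrome of secretory granules, was led by an unannotated NIC model of 6 exons at 105933702 to 105940378 on chromosome 11 (57.4% and 54.9%), ahead of Cyb561-201 (19.7% and 14.1%). Rps24 was read as Rps24-210 (48.7% and 46.4%) and as an unannotated NNC model of 6 exons on chromosome 14 from 24490681 to 24495858 (38.3% and 39.3%).

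Isoform shares differed between the libraries in 31 of 2799 genes tested (1.11%; Fisher's exact test, Benjamini-Hochberg adjusted p under 0.05), and in 10 of them the leading isoform held more in replicate 2. Without adjustment, 196 genes had a p under 0.05, and a simulated chi-square test over all isoforms called 59 genes. The gene with the widest gap was Atf4, a transcription factor of the stress response. Atf4-201 held 32.1% of its full-length reads in replicate 1 (61 of its reads; 95% Wilson interval 25.9% to 39.0%) and 91.2% in replicate 2 (52 reads; 81.1% to 96.2%), with an adjusted p of 2.3e-13 in Fisher's exact test. The rest were the retained-intron transcript Atf4-203, of 1 exon. Slc25a25-205 held 82.4% and 23.9%, Sf3b1-201 26.5% and 82.6%, Ubqln1-202 86.2% and 42.9%, and Tpm1-212 8.59% and 50%. For Dus1l, an unannotated NIC model held 0 and 21 full-length reads, beside 48 and 30 reads of other isoforms. Of the 26 steroid, medulla and isoform panel genes with enough reads, 22 had a leading isoform over 50% in both libraries, 6 had at least 2 isoforms at 10% or more in both libraries, and 1 differed. That was Hsd3b1, where Hsd3b1-201 held 59.9% and 35.3% (adjusted p of Fisher's exact test 0.0032), on 603 of its 10967 reads and 85 of its 4427 reads. The most read models of Hsd3b1, classed as ISM, were outside this test.

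Spliced models outside the annotation recurred when they were read often. Of the NIC models of replicate 1 with at least 2 reads, 47.0% (95% Wilson interval 45.5% to 48.5%) had their intron chain in replicate 2, and of the NNC models 38.1% (36.4% to 39.7%). In the other direction the shares were 80.6% (78.5% to 82.5%) and 75.8% (73.2% to 78.3%), with the deeper library as the target. At a minimum of 10 reads the shares for both classes together were 90.3% and 95.1%. Counting models from 1 read upward, 5336 of them, 3138 NIC and 2198 NNC, from 3155 genes were in both libraries. The most read was a NIC model of Oaz1, the antizyme that limits polyamine synthesis, with 5 exons on chromosome 10 from 80826656 to 80829290. It held 2246 reads in replicate 1 and 951 in replicate 2, or 96.4% and 96.8% of the full-length reads of the gene. All introns of this model are annotated. An NNC model of the mitochondrial ribosomal gene Mrpl33, on chromosome 5 from 31613939 to 31622637, held 374 and 252 reads. It contains an intron at 31614031 to 31616380 that is outside the annotation. Models of Mpc1, a subunit of the mitochondrial pyruvate carrier (336 and 162 reads), and Phb2 (304 and 97) held 94.6% and 95.9%, and 97.4% and 99.0%, of full-length reads. That of Cdkn1c held 466 and 112 reads, 24.4% and 25.8% of full-length reads. The others were in Idh3g (382 and 96 reads), Cd47 (310 and 68) and Oaz2 (288 and 87). The models of Phb2, Cdkn1c, Cd47 and Oaz2 also hold only annotated introns. Those of Mpc1 and Idh3g each hold 1 intron outside the annotation.

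Loci outside annotated genes were mostly of 1 exon. There were 15852 such loci in replicate 1 and 9630 in replicate 2, of which 28.4% and 45.8% overlapped a locus of the other library on the same strand. Antisense loci held 3.61% and 3.98% of all reads and intergenic loci 0.743% and 1.00%, and models of 1 exon held 88.8% and 92.4% of their reads. The 4 most read loci found in both libraries were all antisense and of 1 exon. The first lies on the plus strand of chromosome 5, opposite the cytoplasmic actin gene Actb, with 2233 and 379 reads. It spans 142901399 to 142903654 in replicate 1 and 142903234 to 142903654 in replicate 2. A pair lies on chromosome 17. Its first member, opposite Gm26917 (1049 and 1163 reads), spans 39843013 to 39846245 in replicate 1 and ends at 39845074 in replicate 2. The second spans 39846353 to 39846958 opposite CT010467.1 (807 and 120 reads), where it also overlaps Gm42418 of its own strand. The last lies on chromosome 4 from 129839151 to 129839678 opposite Ptp4a2 (632 and 137 reads).

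Short transcripts were relatively higher in replicate 2. Genes whose leading annotated transcript was under 1 kb had a median log2 ratio of 0.35 over 1107 genes (bootstrap 95% interval 0.31 to 0.39), against -0.043 for 2402 genes of 1 to 2 kb, -0.15 for 2324 genes of 2 to 3 kb and -0.043 for 3501 genes over 3 kb. The share of ISM reads in these classes was 6.603%, 10.9%, 11.7% and 15.8% in replicate 1 and 8.90%, 15.1%, 24.4% and 14.4% in replicate 2. Cyp11a1, with its transcript of 2120 nt, lies in the class of 2 to 3 kb, and without it that class held 12.1% and 12.6%.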

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

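Of the tests in this part, the mirrored-intron share of antisense models was set before its result was seen. The positions and counts of loci on the Y chromosome and opposite Actb were picked out after the data were seen.

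Reads outside annotated genes appeared on the Y chromosome although the labels give female mice, with 78 reads in replicate 1 and 39 in replicate 2. These reads are sums over 19 and 9 loci, to which the floor of 3 reads for a single count of 0 does not apply. Whether they also align elsewhere in the genome was not tested. The main locus, at 43918756 to 43923547 on the minus strand, held 31 reads in replicate 1 and 23 and 5 in 2 pieces in replicate 2. The annotated Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had 0 reads in both libraries.

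Reads of 1 exon opposite Actb, outside the gene comparisons, numbered 2233 in replicate 1 and 379 in replicate 2, above the 3 reads that a count of 0 allows. Across all antisense loci, 94.4% and 95.0% of reads were of 1 exon, without splice sites to tell the strand. A candidate explanation is that reads of the sense transcript were given the wrong strand. Of 3362 reads of multi-exon antisense models, 43.7% (95% Wilson interval 42.1% to 45.4%) had every intron at the position of an annotated intron of the other strand. This lies between the limits set beforehand (over 50% if so, under 10% if not). The test therefore does not decide between wrong strands and true antisense transcripts for the multi-exon reads as a set. The 1470 reads with every intron mirrored had the intron positions that a wrong strand gives. Reads of 1 exon, among them those opposite Actb, hold no intron and were outside the test. No biological explanation was tested.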

How the results depend on the processing

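Models of more than 1 exon for gene tests and for the cortex to medulla ratio, any 2 isoforms, and the settings without Cyp11a1 were chosen after the data were seen, and the other settings before. For every value that changed, the cause was not tested, unless the setting itself removes reads or genes. Matching unannotated models by identifier was not run, since no identifiers are shared.

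The count of genes whose reads differ (1383) stayed between 1008 and 1391 under both other scalings, other minimums, full-length reads, no Genomic class, equal depth and models of more than 1 exon. It was 750 when an absolute log2 ratio of at least 1 was required. As a share of the genes tested, calls moved more, from 14.0% to 26.0% at a minimum of 50 reads (1292 of 4965) and to 7.09% with no minimum (1202 of 16945). Total reads as scaling called 1378 genes, 1256 of them shared, and put 47.2% of calls higher in replicate 2 against 56.2%. This share was 48.8% at equal depth and 49.5% in models of more than 1 exon. Genes in both libraries were 7960 at a minimum of 5 reads. Pearson's r was 0.850 at a minimum of 50 reads and 0.842 in full-length reads. At a mean CPM of at least 10, 5 of 23 lists lay outside the central range, and 2 or 3 of 26 did under the other settings. The cortex to medulla ratio was 4.49 in full-length reads, 45.0 as a ratio of medians (63.4 in replicate 1 and 26.6 in replicate 2), and 5.72 to 9.60 as a ratio of sums with either library alone, where replicate 1 gave the lower value.

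Genes with a second isoform (593 of 3015) numbered 892 at a share of 5%, 288 at 20%, 597 with any 2 isoforms at 10%, and 81 of 615 at a minimum of 100 full-length reads. In either library alone they numbered 779 to 1742, the lower count over 3029 genes with enough reads in replicate 2 (25.7%) and the higher over 5740 in replicate 1 (30.3%). Isoform usage differed in 20 of 576 genes at a minimum of 100 reads (15 shared) and in 59 of 1628 by a simulated chi-square test over all isoforms (29 shared), against 31 of 2799. Unannotated models were found in the other library for 77.7% and 90.3% (replicate 1) and 95.2% and 95.1% (replicate 2) at minimums of 5 and 10 reads, against 43.2% and 78.7% at 2. Known models held 80.9% of the reads of models with more than 1 exon.

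A turn of direction was counted only where a gene was past the threshold over all reads or under the setting compared. By this rule, ratios of named genes turned direction in full-length reads for Cyp11a1 (-0.14), Hsd3b1 (-1.23), Akr1c18 (-0.12), Atp5b (-0.64), Akr1cl (-0.015), Apoe (-0.11), Aldoa (0.051) and Abcb1b (0.41). They turned for Hsd3b1 (-0.034) and Apoe (-0.38) without the Genomic class, and for Cyp11a1 (-0.078), Hsd3b1 (-0.076) and Apoe (-0.13) in models of more than 1 exon. Leaving out the Genomic class removed reads unevenly, since it held 0 and 952 reads of Apoe and 11568 and 2 of Cyp11a1. The ISM class, which stayed in, held 507 and 7 reads of Apoe and 1775 and 13996 of Cyp11a1. For these genes that setting does not compare like reads. Under DESeq2 size factors all 106 named genes tested kept their side of the threshold without such a turn. Genes past the threshold in neither setting count as kept whatever their sign. In full-length reads, for example, Cyp11b1 went from 0.043 to -0.0019 and Nr2f2 from -1.06 to 0.0075. Fewer genes were tested in full-length reads, without the Genomic class and in models of more than 1 exon. Under total reads 100 did, 2 lost the call (Atp5b and Car3) and 4 gained one (Cyp21a1, Dcn, Nr2f2 and Bst2). At equal depth 99 did, 6 lost it (Aldoa, Car3, Cfd, Msmo1, Emcn and Dab2) and 1 gained it (Dcn). In full-length reads 87 did, 8 turned, 5 lost the call (among them Prdx2, Dhcr7, Msmo1 and Emcn) and 4 gained one (Cyp21a1, Prdx1, Tef and Bst2). Without the Genomic class 94 did, 2 turned, 4 lost the call (Star, Aldoa, Msmo1 and Emcn) and 4 gained one (Cyp21a1, Prdx1, Eng and Hba-a1). In models of more than 1 exon 84 did, 3 turned, 2 lost the call (Prdx2 and Emcn) and 3 gained one (Cyp21a1, Prdx1 and Dcn). Mean levels moved by more than 1 SD in 47 of 120 genes in full-length reads. Depth limits replicate 2, where 3 reads equal 7.24 CPM. No paired analysis was possible because the design holds 1 group.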

Other observations

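Of the tests in this part, those of the spike-ins were chosen only after their results were seen, and the muscle and truncation tests were set before theirs.

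Most genes known from skeletal muscle were read more in replicate 1 than in replicate 2. Of 29 further muscle genes listed before their reads were looked up, 25 had a read in replicate 1 and 9 in replicate 2, led by the enolase Eno3 (61 and 10 reads), Cox6a2 (47 and 6), the myosin light chain Myl1 (44 and 3) and myoglobin, Mb (32 and 0), while Pygm (30 and 13 reads, or 26.2 and 31.4 CPM), Actn3 (8 and 3) and Tnni1 (2 and 1) were not lower per 1000000 reads in replicate 2, and the fast myosin Myh4 had 0 in both. Replicate 2 held 9.13% of their pooled reads (39 against 388 in replicate 1), where depth alone would give 25.6%, and 8.15% without Eno3. The 95% Wilson interval reaches up to 12.2%, which argues against the smaller depth of replicate 2 as the cause. Cells of skeletal muscle in the tissue piece of replicate 1 remain a candidate explanation, how the glands were dissected is not given in the sources used here, and no biological explanation was tested.

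Short transcripts were relatively higher in replicate 2. More RNA truncated at the 5' end in replicate 2 was predicted to raise its excess of ISM suffix reads most in long transcripts. The excess was 2.55 percentage points under 1 kb and 0.606 over 3 kb, a difference of -1.94 (95% interval -2.23 to -1.65, and -2.16 without the 20 most abundant genes). The prediction was thus not met in suffix reads, although the excess over 3 kb stayed above the bound of 0 set beforehand. This does not decide on truncation, because reads cut back to 1 exon can fall outside the suffix subtype. Over 3 kb, Genomic reads were 9.21% in replicate 1 and 14.7% in replicate 2, Known reads 67.7% and 63.2%, and all ISM reads 15.8% and 14.4%. Under 1 kb, they were 2.73% and 2.38%, 86.8% and 85.4%, and 6.60% and 8.90%. A length dependence of library preparation or sequencing stays open, since the 19 of 33 spike-in RNAs under 1 kb took 31.9% of the reads in replicate 1 and 43.3% in replicate 2, but 18.2% and 23.0% without the most read of them, and 9 of the 19 were relatively higher in replicate 2 and 10 lower, with a slope of -0.20 log2 per kb over spike-ins (95% interval -1.05 to 0.64) beside -0.29 over genes of that length range. Over these RNAs, of 274 to 1156 nt, Spearman's rho of the log2 ratio with length was -0.234 (permutation p 0.191, adjusted 0.382) and Pearson's r was -0.0845 (permutation p 0.643, adjusted 0.643; -0.0939 without the 2 farthest in length), which does not decide it, and no biological explanation was tested.

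In full-length reads Nr4a1 kept its direction, with a log2 ratio of 3.09.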
